A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

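RNA from 36 cultures of the haploid yeast strain BY4741 was measured on Affymetrix Yeast Genome 2.0 arrays. Per the labels, exponential cells in minimal medium were kept for 2 h with the IC20 of 1 of 6 pesticides or without it, and each pesticide had control cultures of its own. The titles of the 3 alachlor IC20 arrays end in a mark (2) that the sources used here do not explain, and these arrays were used as the alachlor IC20 group. The 12 groups hold 3 arrays each. The doses were 200 mg/L alachlor, 160 mg/L carbofuran, 80 mg/L diuron, 115 mg/L MCPA-ME, 20 mg/L pyrimethanil and 220 mg/L S-metolachlor. RNA was extracted with hot phenol and labelled with biotin by in vitro transcription, per the labels' protocols.

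The deposited values are probe set intensities on a linear scale, which the authors made with Affymetrix Expression Console (version not given in the sources used here). The normalization between arrays and the summary of probes into probe sets are not given in the sources used here. The intensities ran from 1 to 39731.7 and the array medians from 1319.6 to 1511.4. Array data carry no counts, so precision is limited by the number of arrays per group. Signs of RNA quality from control probe sets were not analysed here.

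The table held 5716 probe sets, of which 5498 were assigned to a single gene by the annotation supplied with the series and 218 had no gene name. Where a gene had more than 1 probe set (47 genes), the one with the highest mean over all 36 arrays was kept, which gave 5449 genes. For 12 genes the symbol was updated through the gene identifier. The 120 genes represented by a probe set with the suffix _s_at or _x_at were tested but are not named as results of their own. Intensities were raised to a floor of 32 and taken to log2. Values under the floor made up 1.778% of the tested values, with 82 to 120 genes per array. The floor was chosen after the range of the values was seen and before any group was compared.

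A linear model with 1 mean per group was fitted over all 36 arrays with limma 3.58.1 in R 4.3.3 (24 residual degrees of freedom, 25.81 after moderation). Each IC20 group was compared with its own control by limma's moderated test, two-sided. Further contrasts set the change with 1 pesticide against the mean change with the other 5, and the change with alachlor against that with S-metolachlor. Levels among the 6 control groups were compared by limma's F test. All p-values were adjusted by Benjamini-Hochberg over the 5449 genes, separately for each contrast, and genes with an adjusted p under 0.05 were called. Log2 changes are IC20 minus control, and intensities are given as mean ± SD of 3 arrays. Changes were correlated across genes between pesticides as a description only, with no p-value, because genes are not independent replicates.

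Groups of genes were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the 40 lists with at least 4 measured members. Each list was also tested with a correlation estimated from the data and with fry, which asks whether a list's genes move on balance 1 way and makes no comparison with other genes. The gene lists, the contrasts, the threshold and the rule for named genes were fixed before the data were examined, from general knowledge of yeast. The genes named per pesticide are the 10 with the largest called change in each direction whose 3 IC20 values all lie beyond all 3 control values, and up to 3 called members of each called list. For each contrast of 1 pesticide with the others the 5 largest in each direction were taken, and for alachlor against S-metolachlor and for the genes changed with all 6 the 10 largest in each direction. Strain markers and the members of the drug resistance, arginine, sulfur and glutathione lists could be named in any case. Genes named outside this rule are identified as such.

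The alternatives fixed in advance were quantile normalization, median centring of each array, adding 16 to the intensity in place of the floor, leaving out the dimmest 25% of genes, all annotated probe sets, all probe sets whether named or not, only the 6 arrays of a pesticide, all 18 controls as 1 group, the replicate number as a block, limma's trend and robust options, array weights (gene-by-gene method), thresholds of 1.5-fold and 2-fold, and leaving out each array in turn. With an array left out its group has 2. With all 18 controls as 1 group the control cancels in contrasts between pesticides, which then compare IC20 groups alone. Chosen after the data were seen were floors of 1 and 100 and a fit without MCPA-ME IC20 array 2 and carbofuran IC20 array 1, the 2 arrays farthest from their groups. Whether equal replicate numbers mark paired cultures was checked by correlating the deviations of control and IC20 arrays across genes. Every pair of equal number correlated above 0.1 for diuron (0.352 to 0.402) and pyrimethanil (0.173 to 0.38) but not for the other 4, so no block was used and the block is an alternative.

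The fit was tested on simulated data with 200 of 5449 genes changed. With equal spread in all groups it recovered 92.5% to 97% of the 2-fold changes, and 3.66% to 6.06% of its calls were false. The measured spread was not equal: the residual SD on the log2 scale was 0.3501 for MCPA-ME IC20, 0.2628 for MCPA-ME control, 0.2619 for carbofuran IC20 and 0.1028 to 0.1869 for the other 9 groups. In simulations with these spreads the shared fit gave 433 false calls for MCPA-ME (69.6% of its calls), 35 for carbofuran (15.7%) and 0 or 1 for each of the other 4. A fit of the 6 MCPA-ME arrays alone gave 6 false calls there (5.41%) and recovered 50.7% of the 2-fold changes, and array weights gave 9 (5.39%) and 76.1%. These simulations led to the counts from a pesticide's own 6 arrays being given beside those of the shared fit, a choice made after the data were seen. Simulated differences between alachlor and S-metolachlor of 2-fold or more were recovered in 93.4% of cases with 10 false calls.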

Results

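Gene expression was measured on 36 arrays, 3 per group, in BY4741, a haploid laboratory strain of mating type MATa. Each of 6 pesticides was given for 2 h at its IC20, the dose described as equitoxic between pesticides, and set against its own control cultures, which the series description says were run together with it. The titles of the 3 alachlor IC20 arrays carry a mark (2) whose meaning is not given in the sources used here. Alachlor, S-metolachlor and diuron are herbicides, MCPA-ME is the methyl ester of the herbicide MCPA, carbofuran is a carbamate insecticide and pyrimethanil is an anilinopyrimidine fungicide. The comparisons ask which genes change with each pesticide and how far the responses are shared. The array medians lay between 1319.6 and 1511.4 intensity units. In 5449 genes, 274 changed with alachlor, 782 with diuron, 877 with pyrimethanil, 1012 with MCPA-ME, 1331 with S-metolachlor and 2298 with carbofuran, by limma at an adjusted p under 0.05. Genes given below with 2 intensities had all 3 IC20 values beyond all 3 control values, unless stated otherwise.

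**Figure D1:**
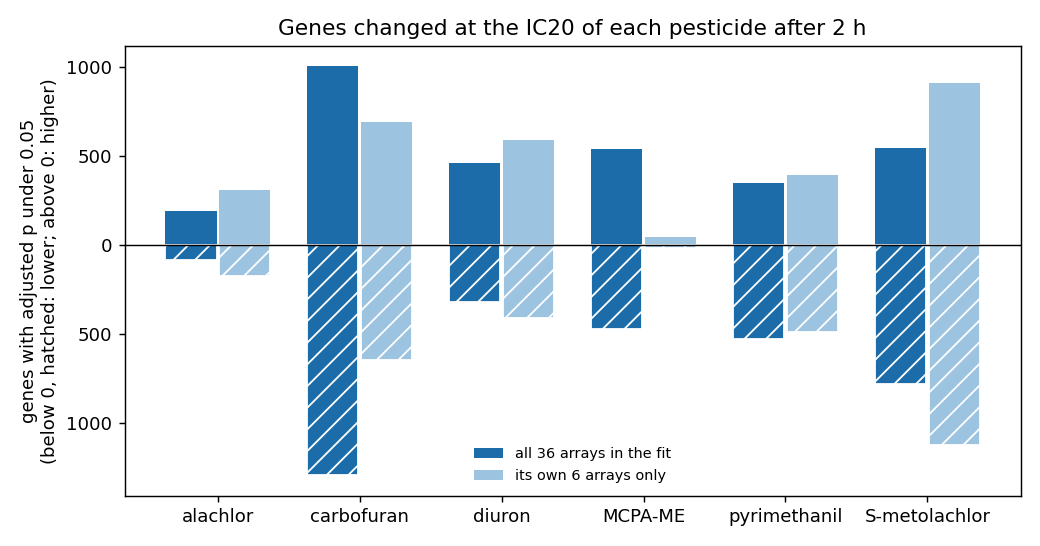
Number of genes called with each pesticide, with genes higher drawn above 0 and genes lower drawn hatched below 0. The bars from the fit of all 36 arrays stand beside those from the pesticide's own 6 arrays; for MCPA-ME the count falls from 543 higher and 469 lower to 48 and 15.

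Alachlor raised genes of drug resistance most. RSB1 (YOR049C), a transporter of sphingoid long-chain bases, rose 20.1-fold from an intensity of 196.9 ± 14.7 to 3964 ± 354 (SD, n = 3; log2 change 4.33, limma adjusted p = 1.63e-16). GRE2, a methylglyoxal reductase, rose 7.24-fold from 2493 ± 109 to 18040 ± 270 (limma adjusted p = 3.39e-20), and the ABC transporter gene YOR1 rose 4.58-fold from 2372 ± 98.4 to 10880 ± 891. INO1, which encodes inositol-3-phosphate synthase, rose by 2.17 on the log2 scale and MPC3, a mitochondrial pyruvate carrier gene, by 2.19. The largest falls were in YBL029W, from 510.6 ± 22.8 to 113.4 ± 13.1 (log2 change -2.18), in the cell wall stress sensor gene WSC4 (-1.89), in EEB1, which makes ethyl esters (-1.88), and in the cell wall mannoprotein gene CWP1 (-1.61).

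Of the 15 measured genes activated by Pdr1 and Pdr3, the regulators of multidrug resistance, 14 rose with alachlor over all genes tested and 15 rose adjusted over the list alone. Their median log2 change was 1.31 (camera adjusted p = 3.7e-48; adjusted p = 7.85e-07 with an estimated correlation). The member left out over all genes was PDR15, with a log2 change of 0.41 and an adjusted p of 0.172. Of 5 aryl-alcohol dehydrogenase genes 2 rose, or 4 adjusted over the list alone (adjusted p = 0.0164 with an estimated correlation), with AAD6 going from 187.4 ± 14.8 to 620.7 ± 24.4. Among 15 genes of the phosphate regulon 6 rose, or 11 adjusted over the list alone (adjusted p = 0.0237 with an estimated correlation), led by the acid phosphatase gene PHO5 (log2 change 1.58) and the transporter gene PHO89 (1.35, no longer called with all 18 controls as 1 group). Of 21 genes under nitrogen catabolite repression, which are kept low on good nitrogen sources, 6 rose, or 14 adjusted over the list alone (adjusted p = 0.0468 with an estimated correlation), among them the ammonium permease gene MEP2 (1.18). The sulfur assimilation list, with 7 of 26 higher (8 higher and 1 lower adjusted over the list alone) and MET28 at 1.72, was called at the preset correlation, with adjusted p = 0.248 with an estimated correlation. In all, 11 lists were called higher and 4 lower with alachlor, and the 4 named before the sulfur list kept the call with an estimated correlation.

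The counts for alachlor were 192 genes higher and 82 lower. The 3 IC20 and 3 control values did not overlap for 30.8% of genes, where chance gives 10%. The higher count was 115 without control array 2; the lower count was 42 without control array 2, 50 without control array 3, 54 without IC20 array 2 and 42 without IC20 array 3. Its own 6 arrays gave 308 and 176, with 233 genes called both ways, and the fit without the 2 arrays farthest from their groups gave 280 and 173.

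S-metolachlor, the other chloroacetanilide, also raised drug resistance genes. RSB1 rose 37.6-fold from 112.8 ± 4.83 to 4237 ± 256 (SD, n = 3; log2 change 5.23, limma adjusted p = 1.44e-18), CIS1 rose 31.7-fold from 152.5 ± 18.8 to 4831 ± 576, GRE2 rose 14.8-fold from 1220 ± 12.2 to 18130 ± 1040 and YOR1 rose 8.7-fold from 1825 ± 190 to 15840 ± 1160. MPC3 rose 14.4-fold from 312.3 ± 9.9 to 4530 ± 750. The deepest fall was in HSP30, a plasma membrane heat shock protein gene, from 8575 ± 4790 to 267 ± 54.8 (log2 change -4.89), and WSC4 fell 13.5-fold from 1370 ± 334 to 100.1 ± 10.9. With all 18 controls as 1 group HSP30, YGR035C (3.87) and TDA6 (-3.07) lost the call, and HSP30 controls of the other experiments averaged from 298 ± 9.24 to 8832 ± 4420.

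All 15 Pdr1/Pdr3 genes rose with S-metolachlor, over all genes and adjusted over the list alone, with a median log2 change of 2.61 (camera adjusted p = 3.47e-38; adjusted p = 6.17e-06 with an estimated correlation). It was the only one of 12 called lists (7 higher, 5 lower) that kept the call with an estimated correlation. Ergosterol synthesis had 12 of 25 higher (13 adjusted over the list alone; adjusted p = 0.0975 with an estimated correlation), including the sterol desaturase gene ERG3 (log2 change 0.79). Nitrogen catabolite repressed genes had 12 of 21 higher and 1 lower, the same numbers adjusted over the list alone (adjusted p = 0.0975 with an estimated correlation), with DAL3 at 2.68 and MEP2 at 1.94. The list of genes induced by weak acids had 8 of 10 lower and 1 higher, also adjusted over the list alone (adjusted p = 0.612 with an estimated correlation). In it PDR12, a pump for weak acid anions, went from 6236 ± 614 to 1592 ± 137. Heat shock chaperones had 9 of 22 lower (10 adjusted over the list alone; adjusted p = 0.612 with an estimated correlation). RPN4, the activator of proteasome genes, rose by 1.53 on the log2 scale.

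The counts for S-metolachlor were 549 genes higher and 782 lower, and values did not overlap for 54.9% of genes (chance 10%). Without control array 1 the lower count was 507 and without IC20 array 3 it was 432. Its own 6 arrays gave 912 and 1121, with 1198 genes called both ways, and the fit without the 2 arrays farthest from their groups gave 862 and 1034.

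Diuron raised RSB1 22.7-fold, from 75.31 ± 5.81 to 1719 ± 223 (SD, n = 3; log2 change 4.51, limma adjusted p = 6.03e-17), and YGP1, a secreted glycoprotein gene, 9.82-fold, from 1067 ± 195 to 10380 ± 748. BNA2, the tryptophan dioxygenase gene that opens NAD synthesis, rose 7.42-fold from 214.3 ± 25.8 to 1586 ± 132 (limma adjusted p = 1.61e-14). The hexose transporter genes HXT4 and HXT2 fell, from 6817 ± 1020 to 894.9 ± 141 (log2 change -2.93) and from 17180 ± 687 to 3978 ± 992 (-2.14), as did MTH1, a regulator of such genes (-1.92). YKR075C fell from 7159 ± 1310 to 980.6 ± 689 (-3.07). ATG40, a receptor for the breakdown of endoplasmic reticulum, rose by 2.28 on the log2 scale and PHO5 by 1.93.

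Of the Pdr1/Pdr3 genes 13 of 15 rose with diuron, or 14 adjusted over the list alone, with a median of 1.34 (camera adjusted p = 2.85e-26; adjusted p = 0.000125 with an estimated correlation); SNQ2 and PDR5, ABC transporter genes, rose by 1.52 and 1.22. Of 16 sporulation genes 5 rose and 1 fell, the same adjusted over the list alone, with a median of 0.26 (adjusted p = 0.0279 with an estimated correlation), and the median after quantile normalization was 0.11. The sporulation genes were near background: DIT1 went from 76.98 ± 8.62 to 203.2 ± 2 and SPR3 (1.04) started below the floor, at 24.48 ± 3.79, and lost the call under quantile normalization. STE3, the a-factor receptor gene of MATalpha cells, rose from 74.44 ± 12.4 to 218.3 ± 23.6, as 1 of 4 MATalpha-specific genes (2 adjusted over the list alone; adjusted p = 0.162 with an estimated correlation). Hexose transporters had 6 of 16 lower, the same adjusted over the list alone; their median was 0 and their mean -0.48 (adjusted p = 0.376 with an estimated correlation). The cell wall integrity list had 7 of 20 higher (8 adjusted over the list alone; adjusted p = 0.376 with an estimated correlation), including the glucan synthase gene GSC2 (1.13). Ribosome biogenesis had 15 of 71 lower (21 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation).

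The counts for diuron were 464 genes higher and 318 lower, with 20 lists called (14 higher, 6 lower), of which 2 held with an estimated correlation; values did not overlap for 40.2% of genes (chance 10%). The lower count was 134 without control array 3, 183 without IC20 array 1 and 184 without IC20 array 2, and all 18 controls as 1 group gave 215 and 157. Its own 6 arrays gave 591 and 411, with 620 genes called both ways, and the fit without the 2 arrays farthest from their groups gave 634 and 495.

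MCPA-ME changed 21 of its 79 named genes both in the fit of all arrays and in its own 6 arrays, and these come first. RSB1 rose 42.3-fold from 168.7 ± 43.6 to 7032 ± 926 (SD, n = 3; log2 change 5.4, limma adjusted p = 6.35e-19), GRE2 rose 6.06-fold from 1958 ± 248 to 11840 ± 984, and YOR1 rose 5.1-fold from 2045 ± 390 to 10440 ± 2050. In the 6 arrays alone the adjusted p was 0.00382 for RSB1, 0.00544 for GRE2 and 0.028 for YOR1. The lysophosphatidic acid acyltransferase gene ICT1 rose by 2.51 on the log2 scale, ATG40 by 2.33 and RPN4 by 0.86. PDR12 fell 7.62-fold from 7390 ± 1310 to 1037 ± 454 (log2 change -2.93; adjusted p = 0.0439 in the 6 arrays alone), HXT2 fell from 13520 ± 1900 to 3127 ± 952 (-2.16; 0.0421) and YBL029W from 1004 ± 177 to 173 ± 63 (-2.58; 0.0369). HXT4 (-2.4) was called in the fit of all arrays and had an adjusted p of 0.128 in the 6 arrays alone.

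All 15 Pdr1/Pdr3 genes rose with MCPA-ME over all genes and adjusted over the list alone, with a median of 2.17 (camera adjusted p = 1.61e-32; adjusted p = 2.36e-05 with an estimated correlation), and 10 of the 15 rose in the 6 arrays alone. This was the only one of 19 called lists (11 higher, 8 lower) that kept the call with an estimated correlation. The Gcn4 list of amino acid synthesis had 21 of 35 lower (22 adjusted over the list alone; adjusted p = 0.447 with an estimated correlation) and arginine synthesis 5 of 7 (6 adjusted over the list alone; adjusted p = 0.447 with an estimated correlation). Genes induced by weak acids had 5 of 10 lower and 1 higher (6 and 1 adjusted over the list alone; adjusted p = 0.447 with an estimated correlation). Ergosterol synthesis had 9 of 25 higher (12 adjusted over the list alone; adjusted p = 0.158 with an estimated correlation). In the 6 MCPA-ME arrays alone limma called 0 members of the Gcn4, arginine and ergosterol lists, with 5 and 1 lower and 5 higher at an unadjusted p under 0.05, and of the weak acid list 2 lower and 1 higher.

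The counts for MCPA-ME depend on the model. The fit of all 36 arrays gave 543 genes higher and 469 lower, but the MCPA-ME groups were the most variable (residual SD 0.2628 and 0.3501). In simulations with such spreads and 200 changed genes that fit gave 433 false calls (69.6%). That share depends on how many genes change, so it is not the share of false calls among the 1012 for MCPA-ME. Its own 6 arrays gave 48 and 15, with 63 of the 63 genes also called in the shared fit, and array weights gave 809 and 851, with 62 genes called in all 3 ways. Values did not overlap for 18.9% of genes (chance 10%). Of the genes called, 53.7% were higher, against 63.9% (682 and 386) with median centring. The lower count was 719 without IC20 array 2, and the fit without this array and carbofuran IC20 array 1 gave 774 and 874; 11 lists were called without control array 3.

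Pyrimethanil raised genes of arginine synthesis, drug resistance genes and some genes of sulfur amino acid synthesis. ARG8, the acetylornithine aminotransferase gene, rose 2.91-fold from 5949 ± 249 to 17310 ± 609 (SD, n = 3; log2 change 1.54, limma adjusted p = 3.46e-08), and STR3, the cystathionine beta-lyase gene, rose 5.17-fold from 119.3 ± 18.9 to 613.2 ± 59.9 (adjusted p = 9.72e-10). RSB1 rose 9.73-fold from 183.4 ± 56.9 to 1723 ± 87.1, and SNO1, of pyridoxine metabolism, rose 3.71-fold from 2416 ± 284 to 8931 ± 105. CAR2, the ornithine transaminase gene of arginine breakdown, fell from 516.6 ± 247 to 113.2 ± 60.5 (log2 change -2.2), the phosphate transporter gene PHO89 fell from 9117 ± 246 to 3397 ± 497 (-1.44), and HES1, an oxysterol-binding protein gene, fell from 149.6 ± 19.8 to 53.04 ± 12.3 (-1.51).

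All 7 arginine synthesis genes rose with pyrimethanil, over all genes and adjusted over the list alone, with a median of 0.78 (camera adjusted p = 1.09e-13; adjusted p = 0.0498 with an estimated correlation). ARG3 (1.43) and ARG4 (0.84) were no longer called with all 18 controls as 1 group. Of 15 Pdr1/Pdr3 genes 10 rose, or 11 adjusted over the list alone, with a median of 0.77 (camera adjusted p = 2.92e-13; adjusted p = 0.0118 with an estimated correlation). Of 15 phosphate regulon genes 12 fell, or 14 adjusted over the list alone (median -0.53; adjusted p = 0.0578 with an estimated correlation), and PHO89 and VTC3 (-0.94), of polyphosphate synthesis, were no longer called with all 18 controls as 1 group. Sulfur assimilation had 12 of 26 higher and 1 lower (13 and 1 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation), with MET28 at 1.76 and the sulfite reductase gene MET10 at 1.32. The respiratory chain list had 11 of 37 higher (14 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation), and the G1/S cell cycle list had 8 of 24 lower, also adjusted over the list alone (adjusted p = 0.575 with an estimated correlation).

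The counts for pyrimethanil were 348 genes higher and 529 lower, with 15 lists called (9 higher, 6 lower), of which 2 held with an estimated correlation; values did not overlap for 41.6% of genes (chance 10%). The share higher was 39.7%, against 51.2% (434 and 414) with quantile normalization and 56.2% (443 and 345) with median centring. The higher count was 207 without control array 1; the lower count was 180 without control array 1, 330 without IC20 array 1 and 265 without IC20 array 2. Its own 6 arrays gave 394 and 489, with 565 genes called both ways, and the fit without the 2 arrays farthest from their groups gave 514 and 784.

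Carbofuran had the highest number of called genes in the fit of all arrays, though in their own 6 arrays S-metolachlor had 2033 and carbofuran 1336. CRC1, the mitochondrial carnitine carrier gene, rose 5.75-fold from 205.4 ± 25 to 1178 ± 73.6 (SD, n = 3; log2 change 2.52, limma adjusted p = 6.48e-12), HSP12, a stress protein gene, rose 7.9-fold from 1246 ± 276 to 10040 ± 3340, and ADH2, the alcohol dehydrogenase gene that is repressed by glucose, rose from 409.6 ± 19 to 2039 ± 151 (2.31). Genes that mark the a mating type fell: AGA2, a subunit of the a-agglutinin, fell 3.94-fold from 7196 ± 362 to 1834 ± 205 (log2 change -1.98, limma adjusted p = 2.13e-12), and BAR1, the protease that degrades alpha-factor, fell from 4169 ± 167 to 1148 ± 151 (-1.87). FUS1, of cell fusion, fell from 1580 ± 66.4 to 482.2 ± 55.9 (-1.72). HUG1, a gene induced by DNA damage, rose from 378.6 ± 18.8 to 1111 ± 83.4 (1.55).

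Of 7 MATa-specific genes 6 fell with carbofuran, over all genes and adjusted over the list alone, with a median of -0.94 (camera adjusted p = 1.68e-08; adjusted p = 0.03 with an estimated correlation). STE2, the alpha-factor receptor gene, fell from 15500 ± 219 to 9275 ± 664, whereas MFA2 had a log2 change of -0.09 and an adjusted p of 0.127. The MATalpha marker STE3 had 119.6 ± 14.1 and 138.8 ± 23.6, with overlapping values and no call, and 0 of 4 MATalpha-specific genes were called. Of 13 pheromone response genes 11 fell, also adjusted over the list alone (adjusted p = 0.0754 with an estimated correlation). Of 21 genes under nitrogen catabolite repression 18 rose, with 18 higher and 1 lower adjusted over the list alone (median 0.97; adjusted p = 0.0291 with an estimated correlation), such as DAL3, the ureidoglycolate lyase gene, from 305.2 ± 27.5 to 1290 ± 103, and the permease genes DAL5 (1.97) and PUT4 (1.98). Of 25 ergosterol genes 19 rose and 2 fell, or 21 and 2 adjusted over the list alone (median 0.42; adjusted p = 0.02 with an estimated correlation), with ERG3 going from 7955 ± 414 to 19130 ± 748 and ERG5 at 1.04. Of 12 DNA damage genes 6 rose, also adjusted over the list alone (adjusted p = 0.0398 with an estimated correlation), including RNR3 (1.4) and RNR2 (0.74) of ribonucleotide reductase; this list lost its call in the 6 carbofuran arrays alone.

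**Figure D2:**
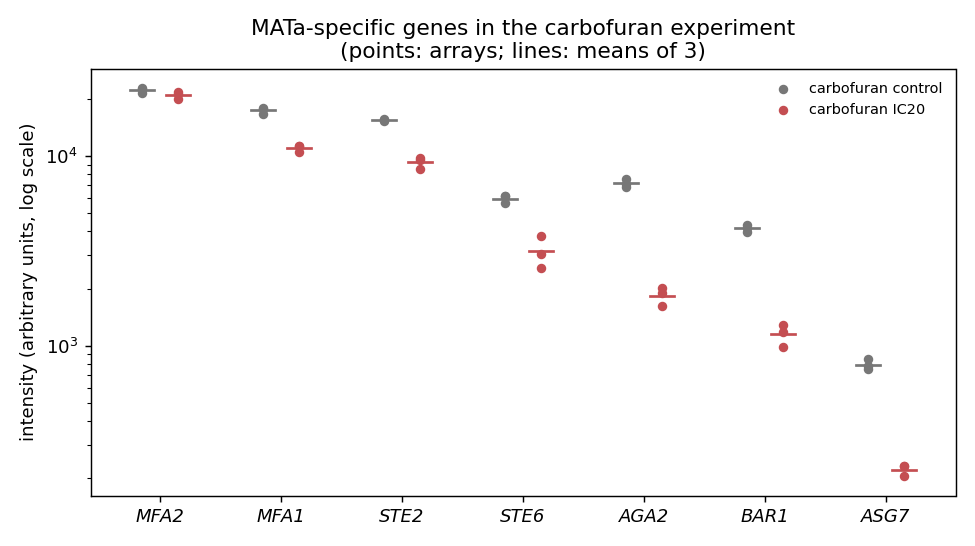
Intensity of the 7 MATa-specific genes on each of the 3 control and 3 carbofuran arrays, on a log axis, with lines at the means of 3 arrays. AGA2 falls from 7196 to 1834 and STE2 from 15500 to 9275, while the MFA2 values lie close together.

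Mitochondrial ribosome genes had 41 of 66 lower and 2 higher with carbofuran (46 and 2 adjusted over the list alone; adjusted p = 0.531 with an estimated correlation), and ribosome biogenesis 36 of 71 lower and 1 higher (37 and 1 adjusted over the list alone; adjusted p = 0.649 with an estimated correlation). The G2/M list had 7 of 14 lower, also adjusted over the list alone (adjusted p = 0.531 with an estimated correlation). Of ribosomal protein genes 35 of 122 were lower and 1 higher (32 and 1 adjusted over the list alone; adjusted p = 0.654 with an estimated correlation), and the sign of the list's median turned with median centring, from -0.04 to 0.05. The Pdr1/Pdr3 list was not called: 6 of 15 genes rose and 5 fell, the same adjusted over the list alone (adjusted p = 0.967 with an estimated correlation), with GRE2 at 1.76 and PDR16 at -1.02 (not called with all 18 controls as 1 group). In RSB1, which rose with the other 5 pesticides, the log2 change was -0.6.

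The counts for carbofuran were 1005 genes higher and 1293 lower, with 17 lists called (9 higher, 8 lower), of which 4 held with an estimated correlation; values did not overlap for 49.8% of genes (chance 10%). The share higher was 43.7%, against 58.5% (1437 and 1018) with median centring. Its own 6 arrays gave 690 and 646, with 1211 genes called both ways. In simulations with the measured spreads and 200 changed genes the shared fit gave 35 false calls (15.7%). That share depends on how many genes change, so it is not the share of false calls among the real ones. The fit without carbofuran IC20 array 1 and MCPA-ME IC20 array 2 gave 1310 and 1732.

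**Figure D3:**
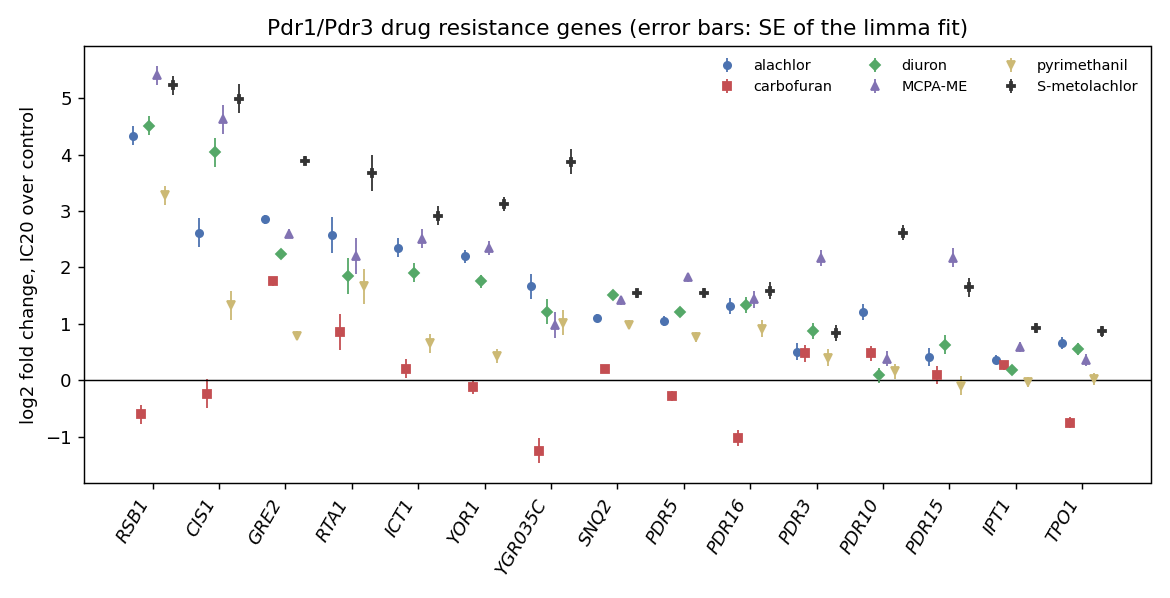
Log2 change (IC20 minus control) of the 15 Pdr1/Pdr3 genes with each pesticide, with error bars of 1 SE of the limma fit. RSB1 changes by 5.4 with MCPA-ME and 5.23 with S-metolachlor but by -0.6 with carbofuran.

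Across the 6 pesticides 35 genes rose and 5 fell with every one, where independence would give 0.00193 and 0.00136. CRC1 rose by at least 0.98 on the log2 scale with each, RTA1 by 0.86, GRE2 by 0.79, BDH2, a butanediol dehydrogenase homolog gene, by 0.7 and DAL3 by 0.65. The 5 that fell were YBL029W (by at least 0.86 in size), MNN1, YDR124W, YCL021W-A and PAM18. Of the 15 Pdr1/Pdr3 genes 3 were among the 35 (GRE2, RTA1 and SNQ2; 0.0963 expected, hypergeometric adjusted p = 0.0031 over 40 lists), as were 3 of 17 genes of the TCA cycle and retrograde response, which include the citrate synthase genes CIT2 and CIT3 (0.109 expected, adjusted p = 0.0031). In 11 of the 40 genes every change was at least 1.5-fold, and in 0 at least 2-fold. The number was 24 with all 18 controls as 1 group, where 16 of the 35 and 2 of the 5 kept all 6 calls. There RTA1 lost its call with carbofuran, BDH2 with diuron and CRC1 with S-metolachlor, and the direction turned for YDR124W with carbofuran (0.36) and pyrimethanil (0.58), SNQ2 with carbofuran (-0.0956) and SER3, chosen after its values were seen, with alachlor (-0.0399). The number was 25 without the dimmest 25% of genes and 72 with array weights. In the 6 MCPA-ME arrays alone 11 of the 35 and 1 of the 5 (YBL029W) were called. CRC1, RTA1 and DAL3 were among those that were not, as were CIT2, CIT3 and DLD3, the 3 of the TCA list. In each pesticide's own 6 arrays 7 and 1 were called with all 6. The hypergeometric test rests on calls of the shared fit and takes genes as independent.

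Changes with carbofuran correlated little across genes with those of the other pesticides. Pearson's r across the 5449 genes lay between 0.0448 and 0.186 for its 5 pairs and between 0.292 and 0.641 for the other 10, with a median of 0.394 over all 15. Pearson's r was highest for alachlor and diuron (0.641, Spearman's rho = 0.503) and Spearman's rho for diuron and MCPA-ME (0.528, r = 0.635). Alachlor and S-metolachlor shared 151 genes higher (19.3 expected), 56 lower (11.8 expected) and 2 in opposite directions, whereas carbofuran and S-metolachlor shared 197 higher, above the number expected, and 141 lower, below it (186 expected), and had 195 in opposite directions. Genes are not independent replicates, so no p-value is given.

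Each change was also tested against the mean change with the other 5 pesticides. Carbofuran differed for 2256 genes (1007 higher, 1249 lower), led upward by CAR2 (difference 3.1) and the aldehyde dehydrogenase gene ALD4 (2.86, limma adjusted p = 1.84e-09), and downward by RSB1 (-5.15, limma adjusted p = 4.21e-17) and CIS1 (-3.75). S-metolachlor differed for 692 genes (352 higher, 340 lower), such as YLL056C (2.36) and HSP30 (-4.86, not called with all 18 controls as 1 group). MCPA-ME differed for 470 (233 higher, 237 lower), among them RSB1 (2.05) and PDR15 (1.64). These 470 rest on the shared fit. For MCPA-ME against its control that fit gave 433 false calls (69.6%) in simulations with the measured spreads and 200 changed genes. False calls of the contrast itself were not simulated with these spreads, so many of the 470 may be false. RSB1 rose nearly as much with S-metolachlor (5.23) as with MCPA-ME (5.4), and the mean of the others includes -0.6 with carbofuran. PDR15 rose by 2.18 with MCPA-ME and 1.65 with S-metolachlor. Pyrimethanil differed for 437 (153 higher, 284 lower), with ARG8 at 1.7 (limma adjusted p = 4.79e-08), INO1 at -2.32 and GRE2 at -1.87. Diuron differed for 287 (176 higher, 111 lower), with BNA2 at 1.89 and EEB1 at 2.54 above the others and HXT4 at -1.54 and MTH1 at -1.95 below. BNA2 also had log2 changes of 1.84 with S-metolachlor, 1.7 with MCPA-ME and 1.5 with alachlor. HXT4 also had -2.4 with MCPA-ME, -1.95 with S-metolachlor and -1.52 with alachlor. Alachlor differed for 18 genes (13 higher, 5 lower), AAD6 among them (1.58, limma adjusted p = 3.56e-07). The number for alachlor was 9 without control array 1, 10 without control array 2 and 9 without either IC20 array 1 or 3. It was 612 with array weights, and 706 between IC20 groups alone (all 18 controls as 1 group). The number for diuron was 190 without control array 2, 165 without control array 3, 162 without IC20 array 1 and 164 without IC20 array 2. The number for MCPA-ME was 738 without IC20 array 2. The number for pyrimethanil was 259 without control array 1 and 267 without IC20 array 2, and that for S-metolachlor 382 without control array 1, 423 without IC20 array 1 and 374 without IC20 array 3. The fit without the 2 arrays farthest from their groups gave 121 for alachlor, 774 for diuron, 866 for MCPA-ME, 1099 for pyrimethanil and 1706 for S-metolachlor.

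Alachlor and S-metolachlor share the chloroacetanilide core and differ in the groups on the ring and on the nitrogen. They were given for the same 2 h at 200 and 220 mg/L, so the doses differ. Set against their own controls, drug resistance genes rose less with alachlor: 10 of 15 Pdr1/Pdr3 genes had a smaller rise by the test of the difference, with a median difference of -0.9 on the log2 scale (adjusted p = 0.000495 with an estimated correlation). Much of this lies in the controls. All 10 had higher control levels in the alachlor experiment, and for RSB1, GRE2, YGR035C, PDR15 and PDR5 the controls differed more than the IC20 levels. With all 18 controls as 1 group the control cancels from this difference, so that setting compares the 2 IC20 groups alone, across experiments. It does not test the part of the controls. There 2 of the 10 passed (CIS1 and PDR10), as did RTA1. The list was called at the preset correlation but not with an estimated one. GRE2 differed by -1.04 (95% interval -1.26 to -0.81; limma adjusted p = 2.73e-06), with controls 1.03 apart and IC20 levels -0.00573 apart. The difference was larger for PDR10, an ABC transporter gene, at -1.4 (-1.79 to -1.01; 8.52e-05), and for CIS1, at -2.37 (-3.12 to -1.62; 0.000521). For 5 of the 15 the difference did not pass: TPO1 had -0.21 (-0.5 to 0.08), PDR3 -0.33 (-0.75 to 0.09), PDR16 -0.28 (-0.7 to 0.15), ICT1 -0.57 (-1.06 to -0.08) and RTA1 -1.1 (-2.02 to -0.18). DAL3 also rose less with alachlor (-1.64, limma adjusted p = 1.21e-05), while HSP30 fell with S-metolachlor and not with alachlor (difference 5.05, limma adjusted p = 0.00705, not called with all 18 controls as 1 group). HSP30 was already low in the alachlor controls: the controls were -4.71 apart and the IC20 levels 0.342 apart. Most of its difference thus lay in the controls. Of the 124 genes with a difference, 59 had a control difference larger than their IC20 difference. The difference passed for 124 genes (58 higher, 66 lower), or 78 without alachlor control array 1, 71 without S-metolachlor IC20 array 3 and 268 in the fit without the 2 arrays farthest from their groups. Array weights gave 858 genes, and the 2 IC20 groups alone (all 18 controls as 1 group) gave 689. Of 1122 genes called with S-metolachlor and not with alachlor, the difference itself passed for 85. The interval lay within ±1 on the log2 scale for 4795 genes (88%), with a median half-width of 0.357.

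The 6 control groups differed from each other. Levels of 4298 genes (78.9%) differed among them by limma's F test, and for 892 of these the highest and lowest control were at least 2-fold apart. HSP30 had the widest range, 4.78 on the log2 scale, followed by SPO19 (4.44), YRO2 (3.95) and YGR035C (3.92); these genes were chosen after their values were seen. Of the 4 marker genes of the strain, LEU2 (66.97 to 194.6), URA3 (6.09 to 24.41) and MET17 (9 to 68.24) had low intensities on every array, whereas HIS3 had 4142 to 11320.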

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

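The tests of control levels, of larger changes with alachlor, of all 4 explanations for the MATa-specific genes, and of normalization and silencing for the sporulation genes were chosen only after the result was seen. The share of genes with a weaker response, the random lists matched on level and the splits of the arrays were planned. All patterns were found and tested on the same data.

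The change of 124 genes differed between alachlor and S-metolachlor. Control levels that differed between the experiments, with IC20 levels alike, are argued against as the whole account. Only 47.6% of these genes had a control difference larger than their IC20 difference, where over 90% would be needed. That share cannot speak against differences between the experiments that also reached the IC20 cultures, since they can make either difference the larger. A single response that was weaker with alachlor is argued against for 5 called genes whose change was larger with alachlor beyond its spread. They were AAD6, ADH7, GTT2, AAD4, which shares probes, and TDH1, whose controls differed more (-0.452) than its IC20 levels (0.105). Their number just meets a bound of 5 set after the signs were seen. A weaker response stays open for the other genes: 53.2% changed the same way and less with alachlor, under the planned bound of 75%. However, 46 of the 56 with opposite signs were not called with alachlor. Noise can set the sign of a change near 0, so that bound was wrong. Either may account for part of the genes, and a difference between the compounds or between their doses in mg/L stays open, since each compound was given in a separate experiment. In the 10 splits of numbered differences, too few for a share under 0.05, the real one gave 332 genes (1 split as large) and the highest other 0.

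MATa-specific genes were lower with carbofuran, with a median of -0.94. Array normalization and any 1 array are argued against as the cause, since the median was -0.85 after quantile normalization and at highest -0.81 when an array was left out. Cells of the other mating type, which would lower all 7 messages alike, are argued against as the whole cause: the falls of MFA2 and AGA2 differed by 1.89 (SE 0.123) and, among the 4 genes under an intensity of 10000 in control, those of STE6 and AGA2 by 1.04 (SE 0.17), a test that replaced one on the level of STE3. A lower message of MCM1, the shared activator, may contribute: MCM1 (chosen after its values were seen) fell from 3719 ± 210 to 1663 ± 639, but the median of the M/G1 list, which Mcm1 also serves, was 0.0296. That value lies above the bound of -0.1 set against this explanation, but members differ with an SD of 0.289, a margin added after the value was seen, so it stays open, and an effect of carbofuran on mating type genes is an untested hypothesis.

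Sporulation genes were higher with diuron, with a median of 0.26. A drift of probe sets near background stays open. The median lay at percentile 99.36 of 10000 random lists matched on level. That percentile cannot decide, because the list was taken up for being called higher in these same values, which made a high percentile likely. Array normalization may account for much of the rise: the median was 0.11 after quantile normalization. Loss of silencing at the mating-type loci cannot be told apart. Of the 4 MATalpha-specific genes 1 (STE3) was called, where 3 were set as needed and 0 as counting against it. That count cannot decide, because a MATa haploid without silencing expresses both mating types, and such cells keep MATalpha-specific genes off. They also keep MATa-specific genes low. The MATa-specific list was not called with diuron, but no bound was set for it, and the lack of a call does not show unchanged genes. Of the MATa-specific genes, AGA2, BAR1 and ASG7 had overlapping values with diuron, while STE2 went from 17120 ± 130 to 15940 ± 442. An effect of diuron itself was not tested further.

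Some genes changed in opposite directions by at least 2-fold with each of a pair of pesticides, and a test of the difference passed for each in the fit of all arrays (log2 difference, first pesticide minus second). There were 20 such genes in 41 pairs of pesticides, and as 11 genes had more than 1 pair, each gene is given only in the pair with its largest difference. Between carbofuran and MCPA-ME these were ALD4 (3.26), SPI1 (2.95), ISF1 (2.61), DUR3 (2.59) and SPO11 (-2.28). Between carbofuran and S-metolachlor they were HPF1 (3.75), AQY1 (2.39), TIR3 (2.39), MTL1 (2.1), PDR16 (-2.61) and YGR035C (-5.12). Between carbofuran and pyrimethanil they were CAR2 (3.98) and HES1 (3.39). For diuron they were YRO2 (4.63) and SOL4 (2.78) against S-metolachlor and EEB1 (3.06) against MCPA-ME. For pyrimethanil against S-metolachlor they were YER053C-A (3.8) and ATF2 (-2.03), for alachlor against pyrimethanil PHO89 (2.78), and for MCPA-ME against S-metolachlor YOR338W (-3.3). For the pairs given, in the 6 arrays of a pesticide alone ALD4, SPI1, ISF1, DUR3 and EEB1 were not called with MCPA-ME. Nor were SOL4 with diuron and YER053C-A with pyrimethanil. For MCPA-ME the shared fit gave 433 false calls (69.6%) in simulations with 200 changed genes. With all 18 controls as 1 group the direction turned for SOL4 with diuron (-0.50), YRO2 with S-metolachlor (0.0401) and YGR035C with carbofuran (0.23), and ISF1, MTL1, PDR16, PHO89, SPI1, YER053C-A and YOR338W lost at least 1 of both calls.

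Some lists were called in opposite directions with a pair of pesticides, and the difference passed as well, all at the preset correlation. There were 9 such lists in 19 pairs, and each list is given only in the pair with its largest median difference. With an estimated correlation 3 of the 27 calls in these pairs held, the phosphate regulon with alachlor (adjusted p = 0.0237), MATa-specific genes with carbofuran (adjusted p = 0.03) and arginine synthesis with pyrimethanil (adjusted p = 0.0498). The others had adjusted p = 0.0578 to 0.839 with an estimated correlation, so every pair lost at least 1 call. Between MCPA-ME and pyrimethanil the median difference was -1.12 for arginine synthesis (adjusted p = 0.0256 with an estimated correlation), -0.39 for the Gcn4 list (adjusted p = 0.15 with an estimated correlation) and 0.29 for fatty acid and phospholipid synthesis (adjusted p = 0.285 with an estimated correlation). Between carbofuran and MCPA-ME it was -1.17 for MATa-specific genes (adjusted p = 0.0166 with an estimated correlation), -1.21 for pheromone response (adjusted p = 0.0262 with an estimated correlation), 0.52 for general stress genes (adjusted p = 0.467 with an estimated correlation) and -0.43 for the proteasome (adjusted p = 0.433 with an estimated correlation). It was 0.94 for the phosphate regulon between diuron and pyrimethanil (adjusted p = 0.0039 with an estimated correlation) and 0.55 for peroxisomal beta-oxidation between diuron and MCPA-ME (adjusted p = 0.0342 with an estimated correlation).

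Of the 218 probe sets without a gene name, which the comparisons do not use, 11 passed with alachlor, 85 with carbofuran, 48 with diuron, 49 with MCPA-ME, 30 with pyrimethanil and 64 with S-metolachlor.

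The 6 arrays of a pesticide can be split in 10 ways, too few for a share under 0.05. The real split gave 274 genes with alachlor, 782 with diuron, 877 with pyrimethanil and 1331 with S-metolachlor, and the highest other split gave 1, 1, 0 and 1; in these 4, and with carbofuran (2298 against 1073), 1 split gave as many as the real one, itself. With MCPA-ME 2 splits did: the real one gave 1012 genes and the split of control 1 with IC20 arrays 1 and 3 against the rest gave 1733, which points to a structure of these samples other than the treatment. For lists the real split and the highest other were 15 and 14 for alachlor, 17 and 15 for carbofuran, 20 and 15 for diuron, 19 and 17 for MCPA-ME, 15 and 12 for pyrimethanil and 12 and 19 for S-metolachlor, where 7 of 10 splits called as many lists. For the other 5 pesticides only the real split, 1 of 10, reached its number of lists.

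For each pesticide against the other 5, 100 splits of 18 differences of equally numbered arrays were drawn. The test used these 18 differences alone, so its counts differ from those of the shared fit. As many genes as in the real split came from 1 of 100 for carbofuran (2021 genes, highest other 12), 2 for MCPA-ME (30, highest other 319), 3 for pyrimethanil (99, highest other 2021), 3 for S-metolachlor (197, highest other 1549), 3 for alachlor (3, highest other 977) and 5 for diuron (23, highest other 369). A second draw gave 1, 2, 2, 2, 3 and 3 of 100 in the same order, with 977 genes in the highest other split each time. These splits hold the effects of the other pesticides, since the 2021 genes in the draws for pyrimethanil came from the 3 carbofuran differences, so they do not measure chance alone and no verdict on chance is drawn for these 6. In the first draw the highest other split held a carbofuran difference for every pesticide, and another structure of the samples was not tested. No other of 100 joint splits gave a gene changed the same way with all 6 (40 in the real one, 1 of 100 as large). These splits break up every experiment at once, and wrong splits of alachlor, diuron, pyrimethanil or S-metolachlor alone called 0 or 1 genes. A joint count near 0 was thus assured, so they cannot tell whether the overlap arose by chance. The highest other split of the 18 controls gave 1450 genes against 4298 (1 of 100), which argues against chance for the control groups, as far as 100 splits can.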

How the results depend on the processing

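The floors of 1 and 100 and the fit without 2 arrays were chosen only after the data were seen; all other alternatives were planned. Directions of named genes did not reverse except with all 18 controls as 1 group, though 8 changes became 0 at a floor of 100 (MEI4 with 4 pesticides, SPR3, MF(ALPHA)1, CLB6 and MET28 with 1 each). With all 18 controls as 1 group 362 values kept direction and call, 129 kept the direction only and 8 reversed. In the 6 arrays of a pesticide 330 kept the call and 89 lost it; under quantile normalization 13 lost it, under median centring 17, with array weights 12, with the replicate block 10 and without the 2 arrays farthest from their groups 9. Of the list calls 84 were lost and 14 held with an estimated correlation, 13 were lost with fry and 14 in the 6 arrays of a pesticide. Except where the construction shows it (fewer genes, fewer arrays, a higher threshold, a wider error), the cause was not tested. Signal over background limits some genes: 82 to 120 genes per array lie under the floor, and other floors ended 16 (floor of 1) or 17 (floor of 100) named calls. The check of RNA quality was not run, and the species of the 218 probe sets without a name was not classed, so they were tested together.

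Quantile normalization gave 32 genes for alachlor against the other 5 (18 in the shared fit), a floor of 100 gave 35 and the replicate block gave 32. Under the replicate block no other count of genes or lists moved by more than 1.5 times, in diuron and pyrimethanil as in the other 4, and 10 named genes and 4 lists lost their call; in diuron these were FUS1, the ribosomal protein list and the purine list, in pyrimethanil INO1, and no other named call changed in these 2 pairs of groups. Median centring gave 345 genes lower with pyrimethanil (529) and 29 for alachlor against the others, and reversed the ribosomal protein list with carbofuran (median 0.0453) and pyrimethanil (0.0148). Without the dimmest 25% of genes, 302 genes were higher with diuron (464), 13 lists were called with diuron (20), 11 genes differed for alachlor against the others and 25 changed with all 6 (40). The median correlation between pesticides was 0.42 among called genes (0.39 over all).

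The 6 arrays of a pesticide gave, higher and lower, 308 and 176 for alachlor, 48 and 15 for MCPA-ME, 912 higher for S-metolachlor and 646 lower for carbofuran. All 18 controls as 1 group gave 616 and 381 for alachlor, 215 and 157 for diuron and 864 lower for pyrimethanil; against the other 5 they gave 706 for alachlor, 775 for MCPA-ME, 1378 for pyrimethanil and 1479 for S-metolachlor, with 689 between alachlor and S-metolachlor and 24 with all 6. They reversed SOL4 with diuron (-0.50), RPN2 (0.0200), RIX1 (0.0630) and YDR124W (0.58) with pyrimethanil, YDR124W with carbofuran (0.36), YRO2 with S-metolachlor (0.0401), and HSP42 (-0.62) and FMP48 (-0.55) for diuron against the others.

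Array weights gave 515 and 367 for alachlor, 1121 and 895 for diuron, 718 and 1318 for pyrimethanil, 1164 and 1535 for S-metolachlor and 851 lower for MCPA-ME. Against the other 5 they gave 612 for alachlor, 1602 for diuron, 733 for MCPA-ME, 1797 for pyrimethanil and 2329 for S-metolachlor, with 858 between alachlor and S-metolachlor and 72 with all 6. The fit without 2 arrays gave 173 lower for alachlor, 495 for diuron and 874 for MCPA-ME, and 862 higher for S-metolachlor. Against the other 5 it gave 121 for alachlor, 774 for diuron, 866 for MCPA-ME, 1099 for pyrimethanil and 1706 for S-metolachlor, with 268 between alachlor and S-metolachlor.

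At least 1.5-fold were 93 and 30 for alachlor, 260 and 582 for carbofuran, 201 and 89 for diuron, 157 and 198 for MCPA-ME, 116 and 148 for pyrimethanil and 186 and 305 for S-metolachlor; against the other 5, 926 for carbofuran, 125 for diuron, 196 for MCPA-ME, 186 for pyrimethanil and 265 for S-metolachlor; with all 6, 11. At least 2-fold were 45 and 9, 75 and 96, 67 and 30, 48 and 75, 35 and 19, and 68 and 83 in the same order; against the other 5, 8 for alachlor, 193 for carbofuran, 39 for diuron, 69 for MCPA-ME, 57 for pyrimethanil and 78 for S-metolachlor; between alachlor and S-metolachlor 46, and with all 6, 0. With an estimated correlation 4 lists were called for alachlor, 4 for carbofuran, 2 for diuron, 1 for MCPA-ME, 2 for pyrimethanil and 1 for S-metolachlor.

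Leaving out 1 array at a time gave, lowest to highest, 115 to 172 genes higher and 42 to 80 lower for alachlor, 689 to 1113 and 899 to 1592 for carbofuran, 338 to 463 and 134 to 290 for diuron, 386 to 708 and 343 to 719 for MCPA-ME, 207 to 327 and 180 to 541 for pyrimethanil, and 389 to 457 and 432 to 622 for S-metolachlor. Lists ranged from 14 to 16, 16 to 20, 17 to 20, 11 to 19, 13 to 15 and 11 to 15 in the same order. Against the other 5 the ranges were 9 to 13 for alachlor, 1549 to 2681 for carbofuran, 162 to 284 for diuron, 333 to 738 for MCPA-ME, 259 to 446 for pyrimethanil and 374 to 632 for S-metolachlor. The pair of chloroacetanilides had 71 to 134 and all 6 pesticides 32 to 47.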

Other observations

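With carbofuran 7 of 23 genes of the iron regulon were higher and 2 lower, the same numbers adjusted over the list alone, and the list was not called (adjusted p = 0.796 with an estimated correlation). FIT2, a cell wall mannoprotein gene that helps retain siderophore iron, rose from 824.2 ± 110 to 4153 ± 872 (SD, n = 3; log2 change 2.32). With S-metolachlor 4 iron genes were higher and 5 lower (4 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.901 with an estimated correlation). The difference between carbofuran and S-metolachlor was not tested for this list. The iron permease gene FTR1 fell with alachlor from 6301 ± 259 to 3054 ± 244 (log2 change -1.05).

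Genes of fatty acid breakdown in peroxisomes moved with diuron, where 6 of 15 were higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.378 with an estimated correlation); CRC1 rose by 1.86 and POX1, the acyl-CoA oxidase gene, by 1.71 on the log2 scale. With S-metolachlor 7 of 17 genes of purine and one-carbon metabolism were lower, also adjusted over the list alone (adjusted p = 0.637 with an estimated correlation), and 6 of 17 genes of the M/G1 cell cycle list were higher (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.637 with an estimated correlation). Oxidative stress genes regulated by Yap1 had 7 of 20 higher with alachlor (9 adjusted over the list alone; adjusted p = 0.0709 with an estimated correlation).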
